A study of Saccharomyces cerevisiae with 13 samples.

How the data were processed

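The 13 samples were 2-colour Agilent tiling arrays, each hybridised with immunoprecipitated (IP) DNA and input DNA of Saccharomyces cerevisiae, of 2 array designs (9 and 4 arrays) with 60-base probes. Per the labels' protocols, ORC was precipitated with a polyclonal antibody to the complex and Mcm2-7 with the antibody UM185, and part of each precipitate was labelled against input DNA by random priming. The scanner files hold each spot's intensity on a linear scale, deposited as written by Agilent Feature Extraction 9.1.3.1 per the file headers, which also record a CGH protocol, background subtraction and a dye normalisation within each array. The authors' value table was taken to hold log2 ratios per array, and no label used here gives its making. Set against the scanner values, 10 of its 13 columns followed the log ratio of the mean signals after lowess. The correlation was 0.965 or more in size (highest 0.999). These columns therefore run as log ratios of IP over input on the dyes used here. A correlation does not give the base of the log. For the second wild-type maintenance array the dye was itself taken from its column, so its sign is not checked by this. For the first wild-type ORC array the size was 0.884, for the first orc6-td maintenance array 0.768 and for the first wild-type maintenance array 0.348. For the last of these the scanner values give neither scale nor direction. The table's columns had medians of 0.003, -0.0002, -0.0007, -0.016, 0.0044, -0.023, -0.0076, -0.018 and -0.024 for the 9 arrays of the first design, in the order ORC wild type, ORC orc6-td, ORC orc6-td in alpha factor, establishment wild type first and second, establishment orc6-td first and second, maintenance wild type and maintenance orc6-td. They were -0.032, -0.035, -0.018 and -0.012 for the second arrays of ORC wild type, ORC orc6-td, maintenance wild type and maintenance orc6-td, so they are centred close to 0. The lowess span and the rule of centring are not given in the sources used here.

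Log2 IP/input was computed from the processed signals, which are already background-subtracted and dye-normalised, and centred on each array's median, with no loess. Control spots and outlier spots were left out, as were spots whose input channel was not well above background. An interval on an array was a run of at least 2 neighbouring probes, at most 1 kb apart, whose 3-probe running mean lay at least 3 robust SDs above the median, the robust SD being the median minus the 16th percentile of the running means. A site of a group was an interval called on both of its arrays, at most 500 bp apart, centred on the highest running mean of the first array. In the 2 groups with 1 array in use, maintenance wild type and ORC orc6-td in alpha factor, a call on that array was enough. The value of a site was the mean over probes within 500 bp of its centre. A change is orc6-td minus wild type, taken within each pair of arrays of the same design and dye orientation and then averaged. ORC changes were read at Mcm2-7 sites and Mcm2-7 changes at ORC sites, so that the sites of the main changes were not chosen on the arrays compared; the few changes given at sites called on the compared wild-type arrays favour lower values in orc6-td. Background windows of 1 kb lay at least 3 kb from any site, and the median change of a site set was ranked, as planned, among 10000 random lists of such windows. All 3 median changes lay below every list, but the windows had medians between -0.09 and 0.04 on the arrays, so they have almost no signal to lose, and the lists leave out the spread between arrays. The ranking therefore does not test the changes. Gene lists and regions were ranked among random lists of genes or windows of the same size. Shared sites were compared with 1000 random placements. Coordinates are those of the array's own annotation, whose genome build is not given in the sources used here, and sites are named by the nearest gene of that annotation.

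These definitions, the lists and the rule for named sites were set before the data were examined. The rule named, per comparison, the 5 sites with the highest wild-type value, and the 5 with the most negative and the 5 with the most positive change among sites that moved the same way on all array pairs and lay more than 20 kb from chromosome ends, and at most 3 genes per list. The lists used were glycolytic, galactose, mating pheromone, heat shock and ribosomal protein genes, windows within 20 kb of a chromosome end, and chromosome 12 from 440 to 500 kb with the ribosomal DNA probes of the second design. Lists of annotated, early, late and silencer origins, of centromeres and of tRNA genes were not used here, because no annotation of them matched to the arrays was used, and neither was the alternative set of all annotated origins. TRP1-GAL3, HML and HMR were added after the annotation had been read.

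The dye that carries the IP came from the labels, with 3 exceptions. The second wild-type ORC array is titled a dye swap but carries the dye label of the first; its ratio was signed to correlate positively with the first array (r = 0.63 over 1 kb bins), as planned. The same rule for the second wild-type maintenance array was not followed: its first array correlated at -0.88, -0.90 and -0.59 over probes with the first orc6-td maintenance, first orc6-td establishment and first wild-type establishment arrays after all were turned to IP over input, so it has no settled direction and cannot serve as the standard. As written, the rule (r = -0.41 over 1 kb bins) would have given the second array the opposite sign. The second array was taken as red over green, as its value column runs, and the first was left out, so that the maintenance comparison used 1 array pair of the second design. Both departures were tried as alternatives.

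Because the second array of a group may be a technical dye swap, each group was taken as 1 replicate and the main results carry no p-value. As a secondary description, with the arrays in place of replicates, limma 3.58.1 in R 4.3.3 was fitted to the site values of 12 arrays (3 residual degrees of freedom) with array design and IP dye as terms, and Benjamini-Hochberg adjusted p under 0.05 was the threshold; these p-values measure only the spread between arrays, which may be technical. Simulated data kept only the probe positions and 1 noise SD of each array, with independent normal noise and planted peaks of a single height. Site calling found 199, 200 and 200 of 200 planted sites on the wild-type ORC, establishment and maintenance arrays with 0, 0 and 2 false sites. Weak peaks and probe or dye effects shared between arrays were left out, so this does not measure recovery on the real arrays. limma called 0, 10, 43 and 50 of 50 simulated sites lowered by 0, 0.5, 1 and 2 log2 units in the ORC comparison. It called 0, 9, 43 and 50 in establishment, and 8, 12, 27 and 44 in maintenance, counted in either direction. The maintenance calls may therefore include unchanged sites. The 4 establishment arrays shared 1 slide, as did the ORC arrays of the first design and the 2 first maintenance arrays, so the establishment pairs and the first ORC pair are within a slide; each array of the second design had a slide of its own. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 did the remaining computation, and matplotlib 3.10.9 drew the figures.

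Alternatives tried were normexp background correction (offset 50), loess within arrays, values in robust SDs, the authors' value table, no filter or a filter on both channels for dim probes, the dye signs as labelled, only the 9-array design, thresholds of 2 and 4 robust SDs, a 5-probe running mean, runs of 3 probes, shared distances of 250 bp and 1 kb, windows of 250 bp and 1 kb to each side, sites of the compared wild-type arrays, limma without terms or on the compared groups alone, and leaving out each array in turn. Chosen after seeing the data were the 2 settings that add the first wild-type maintenance array, with its sign as labelled or turned, and the setting with both wild-type maintenance arrays signed as labelled. The setting with the authors' value table also included that first array, by its value column.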

Results

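Chromatin immunoprecipitation followed by hybridisation to tiling arrays mapped the origin recognition complex (ORC, the 6-subunit complex that marks replication origins) and the Mcm2-7 complex (the replicative helicase that is loaded at origins in G1 to form the pre-replicative complex) across the genome of budding yeast, Saccharomyces cerevisiae. Wild-type cells were compared with an orc6-td strain, in which the Orc6 subunit of ORC carries a degron tag so that it can be removed from the cell. The study's design text gives its question as the effect of losing Orc6 on the establishment and on the maintenance of pre-replicative complexes. The 13 arrays formed 7 groups. ORC was precipitated from cells held in G2/M with nocodazole, a microtubule poison, from wild type (2 arrays) and orc6-td (2 arrays), and from orc6-td cells held in G1 with alpha factor, the mating pheromone (1 array). Mcm2-7 was precipitated from alpha-factor cells of the establishment experiment (2 wild-type and 2 orc6-td arrays) and of the maintenance experiment (2 wild-type and 2 orc6-td arrays). The first of the 2 wild-type maintenance arrays was left out because the direction of its ratio was not settled. The second array of each pair is titled a dye swap, and no label says that it came from a separate culture. Each group therefore counted as 1 replicate, values are given per array pair, and the small number of arrays limits the precision. The median mean signal of the IP channel lay between 436 and 15031 intensity units, the highest on the array left out, and at least 97.8% of the probes were well above background in either channel of every array. The arrays carry no measure of how much Orc6 was left in the orc6-td cells.

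In wild-type cells ORC was found at 189 sites on both nocodazole arrays, and Mcm2-7 at 350 sites on both establishment arrays and at 274 on the 1 maintenance array used. A call in maintenance thus met a looser rule. Some of the 274, such as those near SRD1 and FLO1, had similar or higher maintenance signal in orc6-td and need not mark Mcm2-7 binding. Nearly all ORC sites carried Mcm2-7 in G1: 181 of the 189 lay within 500 bp of an Mcm2-7 establishment site, against a mean of 35.9 and a maximum of 55 in 1000 random placements. In the other direction 191 of the 350 Mcm2-7 sites lay within 500 bp of an ORC site. ORC sites had a median spacing of 56.2 kb, and 170 of them (89.9%) had their centre outside genes, where 32.4% of the probes lie. The strongest ORC signal at an Mcm2-7 site lay on chromosome 4 between 702399 and 703889, in the divergent promoter of ECM18 and SWF1 (SWF1 encodes a palmitoyltransferase), at a log2 IP/input of 4.23. It was followed by SEC20-LCD1 on chromosome 4 (LCD1 encodes the partner of the checkpoint kinase Mec1) at 4.14, the promoter of the isocitrate lyase gene ICL1 on chromosome 5 at 4.05, the promoter of the ferric reductase gene FRE4 on chromosome 14 at 3.82 and the promoter of the transketolase gene TKL1 on chromosome 16 at 3.74. Mcm2-7 signal was highest, among ORC sites, near PES4 on chromosome 6 (3.15), FLR1 on chromosome 2 (2.88), ECM10 on chromosome 5 (2.86), DCG1 on chromosome 9 (2.85) and IFM1 on chromosome 15 (2.79). Of the 350 establishment sites, 258 lay within 500 bp of a maintenance site, and wild-type Mcm2-7 signal in the 2 experiments correlated across the 189 ORC sites, which are not independent replicates, with a Pearson r of 0.91. These maintenance values hold for the direction taken for the wild-type maintenance array. As labelled that array held 1 site, and the correlation would be negative. The number of ORC sites depended on the second wild-type ORC array, without which 446 sites were called, 331 of them near an Mcm2-7 site. With that array's ratio signed as its dye label has it, no site was shared by the pair.

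**Figure D1:**
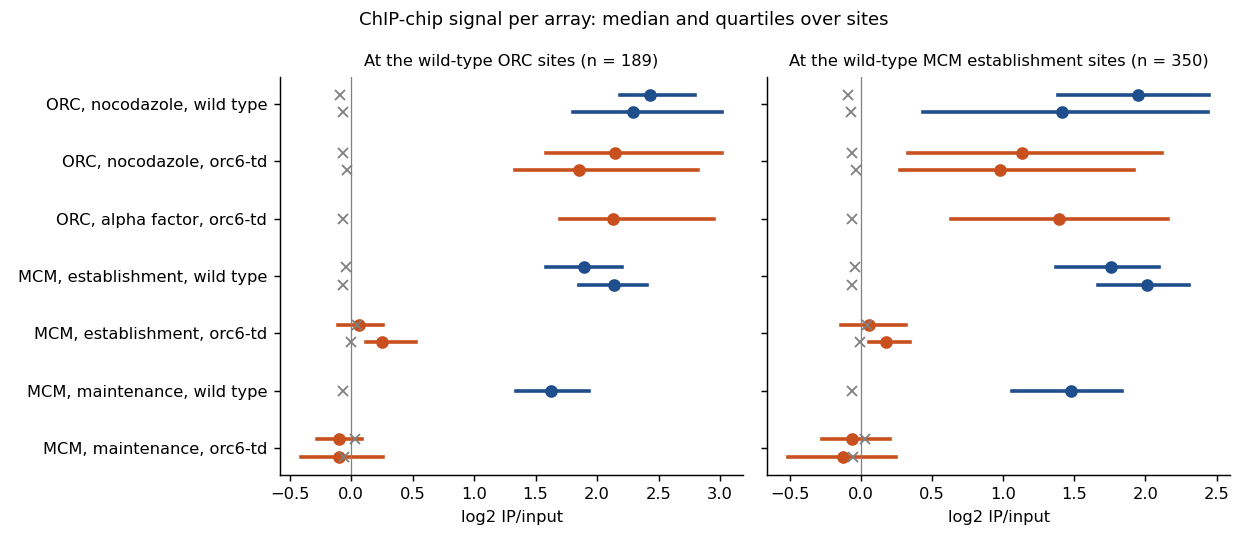
Median log2 IP/input of each array (points) with the quartiles over sites (bars) at the 189 ORC sites and the 350 Mcm2-7 establishment sites, wild type in blue and orc6-td in orange, and the median of the background windows as a cross. At the ORC sites the wild-type Mcm2-7 arrays lay at 1.90, 2.14 and 1.62 and the 4 orc6-td Mcm2-7 arrays at 0.06, 0.25, -0.10 and -0.10, while every ORC array lay at 1.86 or higher.

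In the establishment experiment Mcm2-7 signal was lower in orc6-td than in wild type at each of the 189 ORC sites. The median signal was 2.02 in wild type and 0.17 in orc6-td, a median change of -1.79 on the log2 scale (quartiles -2.02 and -1.54, n = 2 array pairs), or 3.45-fold lower. The 2 array pairs, all on 1 slide, gave -1.78 and -1.77. Signal was lower on both pairs at 189 of 189 sites and lower by 2-fold or more at 173. Only 36 Mcm2-7 sites were called on both orc6-td arrays, 12 of them within 500 bp of a wild-type site, and the number rested on the pair, with 78 on the first array alone and 192 on the second. Near SLX4 on chromosome 12, which encodes a subunit of a structure-specific endonuclease, the signal went from 2.55 to -0.15. Near DCG1 on chromosome 9 it went from 2.85 to 0.16 and near YBL039W-A on chromosome 2 from 2.31 to -0.24. It went near the chitin deacetylase gene CDA1 on chromosome 12 from 2.54 to -0.01 and near ECM10, the gene of a mitochondrial Hsp70, from 2.86 to 0.36. Among the other strong sites, FLR1, a drug transporter gene, went from 2.88 to 0.51 and IFM1, the gene of a mitochondrial translation initiation factor, from 2.79 to 0.89. Near PES4 (chromosome 6, centre 199561), the strongest wild-type site, the signal was 3.15 in wild type and 1.58 in orc6-td.

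The 5 smallest changes more than 20 kb from chromosome ends were at sites with wild-type Mcm2-7 signal below the median of 2.02. The divergent promoter of YKR011C and PRY2 on chromosome 11 carried ORC at 2.42. Within 500 bp of the ORC centre it held almost no Mcm2-7, 0.18 in wild type and -0.04 in orc6-td. A wild-type Mcm2-7 establishment site was still called in its wide ORC interval or within 500 bp of it. Near RRN6 on chromosome 2, which encodes an RNA polymerase I core factor, Mcm2-7 signal was 1.02 in wild type and 0.14 in orc6-td. Near HMRA2 on chromosome 3 the values were 1.39 and 0.50, near MIP6 on chromosome 8 1.16 and 0.25, and near the bud-site gene BUD5 on chromosome 3 0.51 and -0.39. Over all arrays, limma called 184 of the 189 sites lower and 0 higher at an adjusted p of 0.05 (184 at an unadjusted p of 0.05), which compares these arrays and not cultures. For SLX4 limma gave -2.70 with a standard error of 0.17 and an adjusted p of 5.97e-05. It gave for PES4 -1.58 with a standard error of 0.44 and an adjusted p of 0.0103, and for YKR011C-PRY2 -0.22 with an adjusted p of 0.239. Without the second wild-type ORC array, which sets the site list, 300 sites were lower by 2-fold or more and limma called 370.

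**Figure D2:**
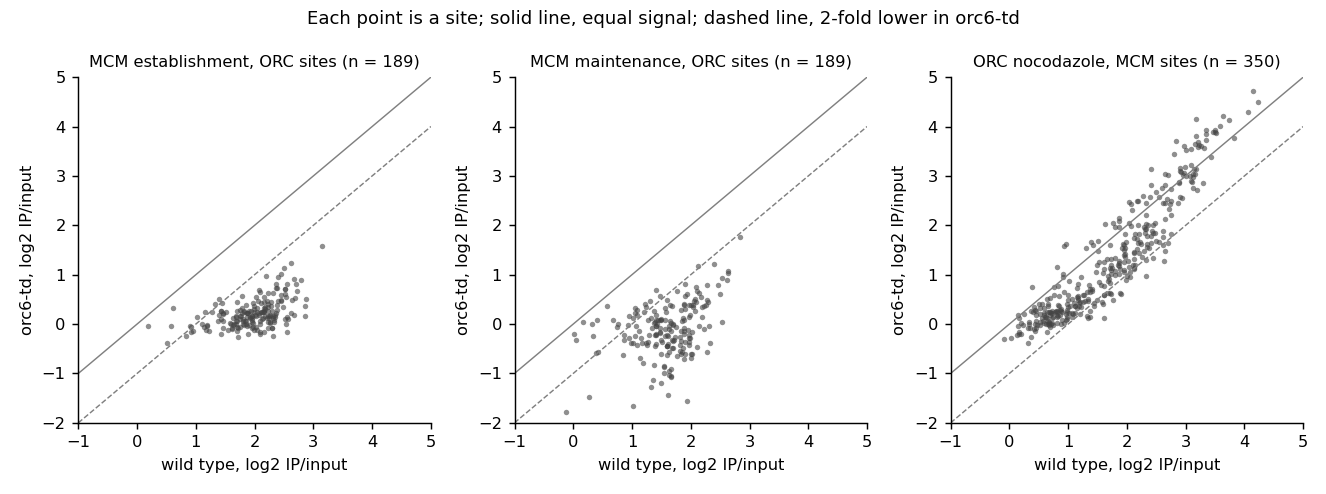
Log2 IP/input in orc6-td against wild type, each point 1 site, for Mcm2-7 establishment and maintenance at the 189 ORC sites and for ORC in nocodazole at the 350 Mcm2-7 sites; the solid line marks equal signal and the dashed line a 2-fold lower signal in orc6-td. All 189 sites lie below the solid line for Mcm2-7 in both experiments, whereas ORC sites with high wild-type signal lie on either side of it.

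In the maintenance experiment Mcm2-7 was lower in orc6-td at all 189 ORC sites of the single usable array pair, with a median of 1.62 in wild type and -0.10 in orc6-td and a median change of -1.66 (quartiles -2.08 and -1.34), or 3.15-fold. Signal was lower by 2-fold or more at 163 sites. The 2 orc6-td maintenance arrays shared 2 Mcm2-7 sites, near FLO1 and YAR075W on chromosome 1, with 163 called on the first array, which had 1959 saturated input spots, and 13 on the second. Some of the strongest wild-type sites had signal in orc6-td too: PES4 went from 2.84 to 1.76, the divergent promoter of YKR105C and YKR106W on chromosome 11 from 2.64 to 1.02, DCG1 from 2.64 to 1.08 and ECM10 from 2.62 to 0.88, while FLR1 went from 2.54 to 0.04. The most negative changes were near YBL039W-A (1.93 to -1.55), YLR404W on chromosome 12 (1.62 to -1.44), TOR2 on chromosome 11 (2.28 to -0.56), the DNA polymerase eta gene RAD30 on chromosome 4 (1.67 to -1.08) and the kinetochore gene NKP1 on chromosome 4 (1.66 to -1.06). The sites with the smallest differences had little Mcm2-7 in wild type: RRN6 at 0.17, YKR011C-PRY2 at 0.02, MIP6 at 0.32, YIL023C-TIM44 on chromosome 9 at 0.04 and JIP5 on chromosome 16 at 0.33, with changes of -0.13, -0.22, -0.32, -0.37 and -0.58. limma, which also used the first orc6-td array, called 178 of 189 sites lower and 0 higher (178 at an unadjusted p of 0.05), but in simulated data it also called 8 of 50 unchanged sites of this comparison.

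The dye labels do not settle the direction of the 1 wild-type maintenance array, which was taken as the likely one. The array is titled a dye swap and carries the dye label of its partner. Taken as red over green, as its deposited value column runs (r = 0.996), it gave the values above. It then held 274 sites, 260 of them within 500 bp of an establishment site, against 1 site as labelled. Over probes it then correlated at 0.82 with the second orc6-td ORC array and at 0.78 with the second orc6-td maintenance array. The dye labels of those 2 arrays match their titles. These arrays are then all red over green on the same design. Shared probe or dye effects could give such correlations, so they do not decide the direction. The place of the 274 sites argues against the direction as labelled. In 1000 random placements a mean of 30.9 and at most 53 of them lay near establishment sites. Taken as labelled the median change was 1.41 with 2 sites lower by 2-fold or more. The partner array correlated at -0.88 over probes with the orc6-td array of the same labelled dye and slide, so neither direction of it was settled. Included as labelled it moved the median change to -0.90 and with its sign turned to -0.85. With both wild-type arrays signed as labelled the change was 0.65. The wild-type and orc6-td arrays of the pair lay on different slides, but at the ORC sites the 4 orc6-td Mcm2-7 arrays, on 3 slides, had medians from -0.10 to 0.25 and the 3 wild-type ones, on 2 slides, from 1.62 to 2.14.

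On the log2 scale the median change was nearly the same in establishment and in maintenance. The difference between them, establishment minus maintenance, had a median of -0.08 over the 189 sites (quartiles -0.32 and 0.18), and the 2 changes correlated across sites with r = 0.78. Median orc6-td signal was near 0 in both experiments (0.17 and -0.10), and wild-type signal correlated between them at 0.91. The correlation of the changes therefore follows in part from wild-type signal and says little about the effect of orc6-td. limma gave a median difference of -0.02 over these sites. Its wild-type maintenance arm was 1 array, of another design than the establishment arrays, so its test cannot show that the 2 changes are equal. The establishment and maintenance changes were -1.58 and -1.08 near PES4, -2.69 and -1.55 near DCG1, -2.37 and -2.49 near FLR1, and -2.55 and -3.49 near YBL039W-A. With the maintenance array signed as labelled the median difference was -3.21, with loess normalisation within arrays -0.46, and with the first wild-type maintenance array added -0.83 as labelled and -0.90 turned. In robust SDs of each array the changes were -6.50 and -2.87 and their median difference -3.69.

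**Figure D3:**
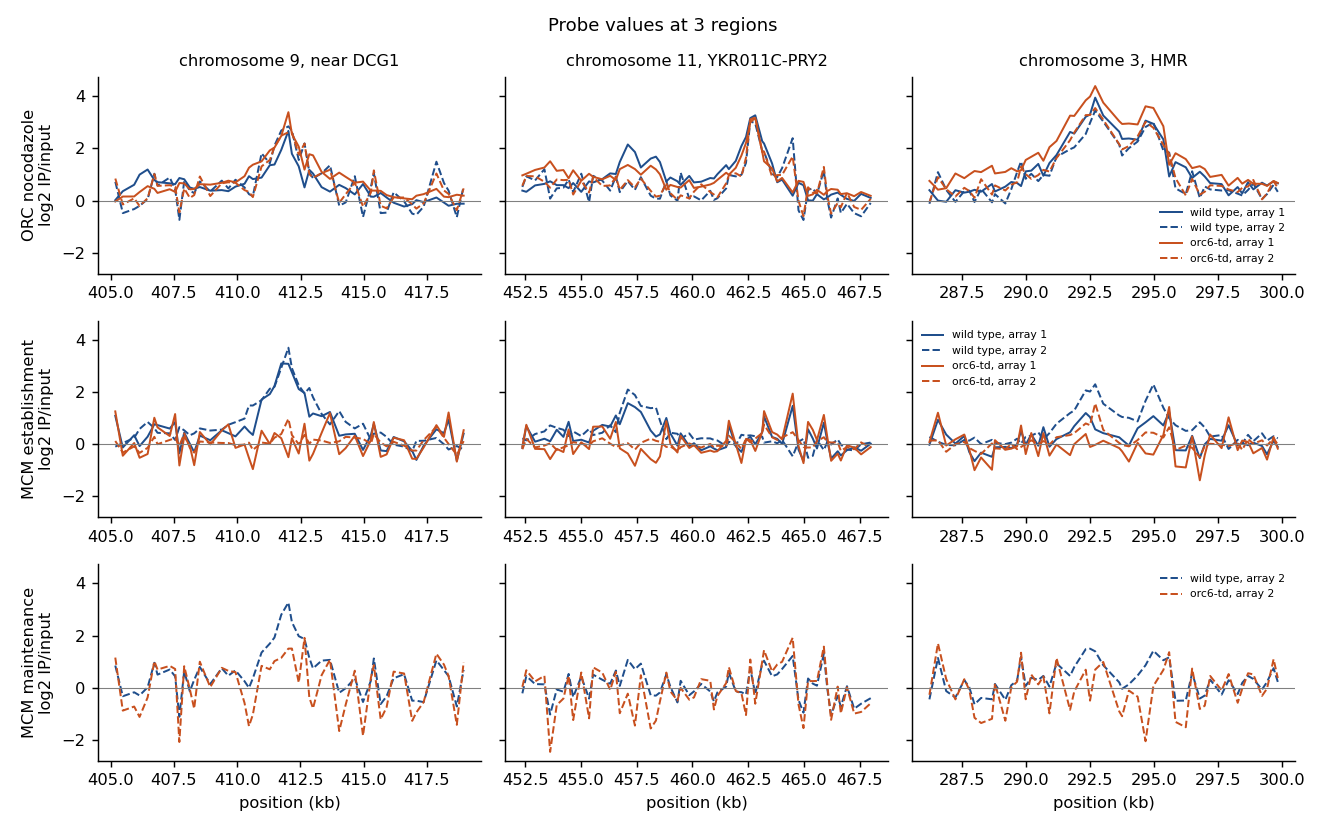
Probe values (log2 IP/input) against position in kb at 3 regions, chromosome 9 near DCG1, chromosome 11 at YKR011C-PRY2 and chromosome 3 at HMR, for ORC in nocodazole, Mcm2-7 establishment and Mcm2-7 maintenance, 1 line per array with wild type in blue and orc6-td in orange. ORC peaks are present in both strains in all 3 regions, the Mcm2-7 peak near DCG1 (2.85 in wild type) is absent from orc6-td in establishment (0.16), and YKR011C-PRY2 carries ORC (2.42) with no Mcm2-7 peak in either strain at its centre.

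ORC was found at mostly the same sites in orc6-td as in wild-type cells held in nocodazole. In orc6-td 196 sites were called, 177 of them within 500 bp of a wild-type ORC site, and 179 of the 189 wild-type sites had an orc6-td site within that distance. At the 350 Mcm2-7 sites, which were chosen on arrays not compared here, the median ORC signal was 1.69 in wild type and 1.05 in orc6-td, a median change of -0.47 (quartiles -0.73 and -0.12, n = 2 array pairs) or 1.39-fold. The first pair, on 1 slide, gave -0.71 and the second, on 2 slides, -0.24, and the change was negative on both pairs at 219 sites and positive on both at 36. The 4 sites lower by 2-fold or more on both pairs were YMR269W, YLR404W and, outside the naming rule and picked after their values were seen, YBR241C-YBR242W on chromosome 2 (1.89 and 0.64) and SRP21-YKL121W on chromosome 11 (2.64 and 1.48). At the 189 ORC sites, called on the wild-type arrays compared, the median change was -0.33.

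Averaged over the 2 array pairs, the strongest ORC sites had as much signal in orc6-td as in wild type, or close to it. ECM18-SWF1 had 4.23 in wild type and 4.49 in orc6-td, SEC20-LCD1 4.14 and 4.73, ICL1 4.05 and 4.29, FRE4 3.82 and 3.76, and TKL1 3.74 and 4.12. The first and second pairs differed in sign at ECM18-SWF1 (0.60 and -0.07), ICL1 (0.57 and -0.09) and FRE4 (0.28 and -0.40). Both were positive at SEC20-LCD1 (0.88 and 0.29) and TKL1 (0.67 and 0.11). Higher values in orc6-td on both pairs were found near YDR506C on chromosome 4 (3.18 and 4.15), PES4 (2.84 and 3.70), the transcriptional repressor gene MIG3 on chromosome 5 (2.42 and 3.13) and the chromatin protein gene SPT2 on chromosome 5 (2.80 and 3.45). None of these passed limma's test (adjusted p 0.0673, 0.176, 0.0588 and 0.0673). The most negative changes were near YMR269W on chromosome 13 (1.62 to 0.12), DCS2 on chromosome 15 (2.33 to 0.97), YLR404W on chromosome 12 (2.63 to 1.28) and the carboxypeptidase gene KEX1 on chromosome 7 (1.90 to 0.60). limma called these at adjusted p of 0.0354, 0.0354, 0.0354 and 0.0373. Near YHR126C on chromosome 8 the values were 1.76 and 0.48 (limma adjusted p 0.0588). Over the 349 sites tested limma called 38 lower and 0 higher, with 128 at an unadjusted p of 0.05. The first pair alone gave 104 sites lower by 2-fold or more and the second alone 12. limma called 0 sites when the first orc6-td ORC array, the second orc6-td ORC array or any 1 of the 4 establishment arrays was left out and 219 without the second wild-type array. With the second wild-type array signed as its dye label has it, the median change was 0.77.

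Mcm2-7 sites without a called ORC site had nearly the same Mcm2-7 change as the rest in establishment, and a smaller one in maintenance. The 159 Mcm2-7 sites with no ORC site within 500 bp had a median Mcm2-7 change of -1.75 in establishment, against -1.74 at the 191 with one. In maintenance the changes were -1.41 and -1.63, for the direction taken for the wild-type maintenance array. The differences between the 2 sets were not tested. Median wild-type establishment Mcm2-7 signal was 1.68 at the 159 sites and 2.01 at the 191, so the 159 had less signal to lose. Both sets were called on the wild-type establishment arrays, which favours lower values in orc6-td in establishment. At the 159 sites ORC signal was 0.85 in wild type and 0.25 in orc6-td, averaged over the 2 array pairs. The pairs differed where ORC was weak. At the 117 Mcm2-7 sites with the weakest ORC signal in alpha factor, the ORC change was -0.92 on the first pair and -0.11 on the second. A drop at ORC-poor sites therefore rests mainly on the first pair. The 8 ORC sites with no Mcm2-7 site within 500 bp, named because they are few and chosen after their values were seen, lay near RRN6, BUD5, YDR542W, YEL073C, KSS1, MIP6, YIL023C-TIM44 and YMR321C. Wild-type ORC lay there between 1.14 (YDR542W) and 2.87 (MIP6), and wild-type establishment Mcm2-7 between 0.51 (BUD5) and 1.18 (YEL073C).

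In alpha factor, on the 1 array of this condition, ORC was present in orc6-td cells at 366 sites, and each of the 189 wild-type nocodazole sites lay within 500 bp of one of them. At those 189 sites the median ORC signal on this array was 2.13, and the 2 orc6-td Mcm2-7 establishment arrays, from the same arrest, had medians of 0.06 and 0.25. Against the orc6-td nocodazole array of the same design and dye, on the same slide, the median ORC change at the 350 Mcm2-7 sites was 0.17 (quartiles -0.10 and 0.41), from 1.14 to 1.39. At the 189 ORC sites it was -0.05. The DCG1 site carried ORC at 2.70 in alpha factor, PES4 at 3.90 around its orc6-td peak (centre 199343) and HMR at 3.87. The difference has no replicate check, and the wild-type counterpart in alpha factor was not analysed here.

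At 3 loci chosen after the annotation of the arrays was read, ORC signal was present in both strains and Mcm2-7 signal was lower in orc6-td. Between TRP1 and GAL3 on chromosome 4 (461921 to 464290), where textbooks place ARS1, ORC was 2.31 in wild type and 1.92 in orc6-td, and establishment Mcm2-7 was 0.91 and -0.03. At the silent mating locus HML on chromosome 3, in an ORC interval of 4966 bp, ORC was 2.82 and 2.51 and Mcm2-7 1.96 and 0.05. At HMR, the other silent mating locus, an ORC interval of 7821 bp carried ORC at 3.21 and 3.65 and Mcm2-7 at 1.39 and 0.50. Maintenance Mcm2-7 was 0.76 and 0.01 at TRP1-GAL3, 1.75 and -0.05 at HML, and 1.31 and 0.47 at HMR.

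The lists of genes where ChIP signal need not come from pre-replicative complexes had median changes between -0.11 and 0.16. Of the glycolytic (12), galactose (6), mating pheromone (13), heat shock (9) and ribosomal protein (118) genes, none was 2-fold different on both array pairs in the ORC or the establishment comparison, and 2 ribosomal protein genes were on the single maintenance pair. In establishment the median changes were 0.02, 0.16, 0.05, 0.05 and 0.03 in that order, at percentiles 18.0, 97.8, 31.4, 36.0 and 0.46 of random gene lists. In maintenance they were 0.08, 0.04, 0.13, 0.10 and -0.07, at percentiles 77.3, 58.6, 93.4, 81.5 and 0.03, and for ORC -0.02, -0.11, -0.09, -0.06 and 0.01, at percentiles 14.2, 2.38, 0.75, 5.32 and 30.8. The triose phosphate isomerase gene TPI1 had the largest glycolytic difference for Mcm2-7 (1.05 and 0.20 in establishment, 0.87 and 0.35 in maintenance). HSP42 had the largest of the heat shock genes in establishment (0.87 and 0.31) and for ORC (a change of -0.45). The lists were not cleared of genes beside ORC sites. Called ORC sites lay downstream of TPI1 (establishment Mcm2-7 2.16 in wild type and 0.33 in orc6-td) and at the HSP42 promoter (1.81 and 0.06). The values of these 2 genes may therefore include signal of those sites. RPS19B had the largest of the ribosomal protein genes (0.70 and -0.16 in establishment, 0.21 and -1.26 in maintenance), the other 2-fold maintenance difference being that of RPL42B (-0.74 and -2.09). The wild-type ORC value of RPS8A (3.42, against -0.11 in orc6-td) and that of PGK1 (0.01 in orc6-td) rested on 1 probe each, among 5 isolated bright probes of the second wild-type ORC array. Windows within 20 kb of a chromosome end had more wild-type signal than random windows for ORC (median 0.35) and establishment Mcm2-7 (0.20), with changes of 0.06 for ORC, -0.17 for establishment and -0.23 for maintenance, at percentiles 100, 0 and 0 of random windows. On chromosome 12 between 440 and 500 kb the changes were 0.03, -0.01 and -0.24, at percentiles 65.3, 8.01 and 0.04.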

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

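The 3 tests on the first wild-type maintenance array in this part were chosen after its values had been seen, and no biological explanation was tested for it.

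The scanner values of the first wild-type Mcm2-7 maintenance array, which no comparison used, stood out because, with the sign turned, they correlated at 0.90 over probes with the first orc6-td establishment array. They held almost no signal at the 189 ORC sites, where the array's deposited value column had a median of 2.43. The scale of that column stays unknown, but at these sites it was positive, like IP over input on the other wild-type Mcm2-7 arrays. A turned dye label alone is argued against, since the median at the ORC sites was 0.11 as labelled and -0.12 with the sign turned, and so is a dim channel, since 97.8% of its probes were well above background in the dimmer channel. A scanner file of an orc6-td Mcm2-7 hybridisation may be the source and cannot be told apart from other mix-ups. With the sign turned the array correlated at 0.90, 0.88 and 0.46 with the 3 orc6-td Mcm2-7 arrays of its design. It correlated at 0.58 and -0.14 with the 2 wild-type ones, so the lowest of the former lies below the highest of the latter. That comparison mixes IP dyes. Among arrays with the IP in red the orc6-td value was 0.90 and the wild-type value 0.58. Among those with the IP in green the orc6-td values were 0.88 and 0.46 and the wild-type value -0.14.

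The ribosomal DNA probes of the second array design, which lie at none of the 189 ORC or 350 Mcm2-7 establishment sites, were noticed because of a wild-type Mcm2-7 maintenance value of 2.38 at position 458717 of chromosome 12, where the value in orc6-td was 0.95 and ORC was 1.80 in wild type and 1.41 in orc6-td. Of the 23 such probes, the 9 with a wild-type Mcm2-7 value of 1 or more had medians of 1.86 in wild type and 0.26 in orc6-td, were lower in orc6-td in 9 of 9 cases and by 2-fold or more in 7, with a median change of -1.43. One of the 274 wild-type maintenance sites (458451 to 460362) was called on ribosomal DNA probes, which also entered the chromosome 12 region. The first design had no value within 500 bp of that site's centre. ORC and establishment sites needed arrays of the first design, so the lack of such sites there does not speak against binding. The 9 probes were picked on the wild-type array compared, which in itself favours lower values in orc6-td. Their ORC medians were 1.46 in wild type and 1.22 in orc6-td, with a median change of -0.003. The other 14 probes had Mcm2-7 medians of -0.17 and -0.55, and the copies of this repeat cannot be separated on the array. With the wild-type array signed as its dye label has it, the direction of these Mcm2-7 values would turn, as for the other maintenance values.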

How the results depend on the processing

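The direction of the Mcm2-7 change in establishment and the presence of ORC sites in orc6-td held under every alternative run, while the size of the ORC change, the counts of orc6-td Mcm2-7 sites and all maintenance results depended on the setting. The cause of a difference was not tested except where the setting removes or turns an array or changes the unit. With the 2 conflicting arrays signed as their dye labels have it, there were 0 wild-type ORC sites (and so 0 near Mcm2-7 sites and 0 orc6-td sites near them), and 1 wild-type maintenance site. That sign gave a median ORC change of 0.77 with 1 site lower by 2-fold or more, a maintenance change of 1.41 with 2 such sites, an establishment-minus-maintenance difference of -3.21 and 0 limma calls in all 3 comparisons. Under that sign the ORC change near YLR404W was 1.22, and the maintenance change was 4.60 near PES4, 3.67 at YKR105C-YKR106W, 3.72 near DCG1, 3.50 near ECM10, 2.58 near FLR1, 0.38 near YBL039W-A, 0.18 near YLR404W, 1.72 near TOR2, 0.59 near RAD30 and 0.60 near NKP1. With both wild-type maintenance arrays signed as labelled, an alternative chosen after seeing the data like the 2 that follow, there were 0 maintenance sites, a change of 0.65 with 0 sites lower by 2-fold or more, a difference of -2.45, and 3 maintenance and 0 ORC limma calls. The changes were then 2.19 near PES4, 1.42 at YKR105C-YKR106W, 1.58 near DCG1, 1.27 near ECM10, 0.76 near FLR1, 0.63 near TOR2 and 0.11 near RAD30. Adding the first wild-type maintenance array as labelled gave 0 maintenance sites, a change of -0.90 with 7 sites lower by 2-fold or more, a difference of -0.83, and 5 maintenance and 0 ORC calls; with its sign turned these were 20, -0.85, 2, -0.90, 102 and 0. Normexp gave an establishment change of -2.07, 14 sites with ORC lower by 2-fold or more, 86 ORC calls and 7 orc6-td establishment sites near wild-type ones. Loess within arrays gave 18 orc6-td maintenance sites, 1 site with ORC lower by 2-fold or more, 1 ORC call, a maintenance change of -1.13 and a difference of -0.46. The authors' value table gave 18 orc6-td maintenance sites, 1 site with ORC lower by 2-fold or more, 9 ORC calls and a maintenance change of -1.45. This setting also brought in the value column of the first wild-type maintenance array. Its maintenance change therefore averaged 2 array pairs and is not the main comparison in other values. In units of robust SDs the changes were -1.17 for ORC, -6.50 for establishment and -2.87 for maintenance, the difference was -3.69 and the alpha-factor ORC change 0.87, with 0 ORC and 0 maintenance calls. The 9-array design alone gave 446 wild-type and 310 orc6-td ORC sites (331 near Mcm2-7 sites, 268 near wild-type ORC sites), 163 orc6-td maintenance sites, 104 sites with ORC and 300 with establishment Mcm2-7 lower by 2-fold or more, and 265 ORC and 384 establishment calls. A threshold of 2 robust SDs gave 453 wild-type maintenance sites, 553 orc6-td alpha-factor ORC sites, 216 orc6-td establishment sites (60 near wild-type ones) and 55 orc6-td maintenance sites; 4 robust SDs gave 12 (5 near) and 0, and runs of 3 probes 14 (5 near) and 1. Windows of 1 kb to each side gave changes of -1.43 and -1.30 in establishment and maintenance and 0 sites with ORC lower by 2-fold or more, and windows of 250 bp a maintenance change of -1.96 and 11 such ORC sites. At the sites of the compared wild-type arrays 298 sites had establishment Mcm2-7 lower by 2-fold or more, limma called 328, and the alpha-factor ORC change was -0.051. limma on the compared groups alone called 6 ORC sites and without design and dye terms 0. Leaving out each array in turn moved the wild-type ORC sites between 189 and 446 (highest without the second wild-type ORC array), and those near Mcm2-7 sites between 181 and 331. It moved the orc6-td ORC sites between 196 and 310, the orc6-td establishment sites between 36 and 192 (12 to 96 near wild-type ones), and the orc6-td maintenance sites between 2 and 163. It also moved the sites with ORC lower by 2-fold or more between 4 and 104, those with Mcm2-7 lower by that much between 170 and 300 in establishment and 161 and 289 in maintenance. The maintenance change ran between -1.66 and -1.40 and the limma calls between 0 and 219 for ORC, 178 and 370 for establishment and 174 and 350 for maintenance. A lone array is then assumed to vary like the other groups. The median ORC change ran from -0.71 to -0.24 and the establishment change from -1.79 to -1.61 in these runs. Of the changes at single named sites, 767 values under the alternatives moved by less than the spread between arrays, 220 by more and 18 turned. The set of all annotated origins was not run. At least 97.8% of probes were well above background on every array, but the first orc6-td maintenance array had 1959 saturated input spots and the lowest median IP signal (436), which limits its ratios. Without it 13 orc6-td maintenance sites and 180 maintenance limma calls were found. No paired analysis was possible because the replicate numbers were given in accession order and pair no cultures. The array pairs were matched by array design and dye instead, and limma carried these as terms.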

Other observations

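Chosen after the results had been seen were the test of the first ORC array pair alone, the test of the share of orc6-td Mcm2-7 sites that lie at wild-type sites, its count without the 5 highest sites, and the ratios of ORC medians with the background subtracted. The conditions for arguing against 2 explanations, highly transcribed genes and the first ORC array pair, were also made stricter after the results; both explanations met the earlier conditions for being argued against, and both are now left open.

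The widest ORC intervals of wild-type cells differed in how much Mcm2-7 they carried within 500 bp of the ORC centre, where all values below were read. Each had a wild-type Mcm2-7 establishment site called in the interval or within 500 bp of it, so low values do not mean that the whole interval lacked Mcm2-7. An interval of 9111 bp near the cadmium transporter gene PCA1 on chromosome 2, close to the chromosome end, had ORC at 2.18 in wild type and 2.35 in orc6-td, and wild-type establishment Mcm2-7 at only 0.83. One of 8848 bp at YKR011C-PRY2 had ORC at 2.42 and 2.37 and Mcm2-7 at 0.18. One of 8664 bp at FRE4 had Mcm2-7 at 1.94 in wild type and 0.26 in orc6-td, and one of 7231 bp downstream of SIR1, a silencing gene on chromosome 11, had ORC at 3.88 and 4.46 and Mcm2-7 at 2.32 and 0.17. Intervals near HXK1 (7450 bp, chromosome 6) and HSP104 (7136 bp, chromosome 12) had Mcm2-7 at 1.97 and 1.82 in wild type and at 0.01 and 0.26 in orc6-td. These 8 widest intervals, which also include HMR and SEC20-LCD1, were picked after seeing their widths.

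Of the 159 Mcm2-7 establishment sites without a nocodazole ORC site nearby, 105 had an ORC site within 500 bp on the orc6-td alpha-factor array. Those 105 had a wild-type ORC median of 1.03 in nocodazole, an orc6-td median of 0.36 in nocodazole and of 0.83 in alpha factor, and an Mcm2-7 change of -1.87 in establishment and -1.76 in maintenance. The other 54 sites had ORC medians of 0.55, 0.06 and 0.26 and Mcm2-7 changes of -1.34 and -0.82. The nocodazole ORC medians of both sets average the 2 array pairs. At the 117 Mcm2-7 sites with the weakest ORC signal in alpha factor, those pairs changed by -0.92 and -0.11. Median wild-type establishment Mcm2-7 signal was 1.90 at the 105 sites and 1.38 at the 54, so the 54 had less to lose. The maintenance changes hold for the direction taken for the wild-type maintenance array. All 159 were called on the wild-type establishment arrays, which favours lower values in orc6-td in that comparison. The split was made on the alpha-factor array itself, which favours higher alpha-factor values at the 105 sites. A call there needed only 1 array, whereas a nocodazole call needed both arrays.

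In orc6-td, 36 Mcm2-7 sites were called on both establishment arrays (78 on the first and 192 on the second), and the highest lay near YGL262W (2.25), YNR071C (2.24), SRD1 (2.02), FLO1 (1.99) and YNR073C (1.91). For these 5, sequence that is missing from the strain or of low copy number may be the cause, since the median input intensity at their 67 probes was 413 against 6551 over all probes on the first array and 826 against 7515 on the second, percentiles 0.16 and 0.24; values of 3.71 and 0.78 on the 2 arrays near YGL262W go with that. Signal at highly transcribed genes stays open: the ribosomal protein and glycolytic genes together, 130 in all, lay at percentile 1.62 of random gene lists in orc6-td Mcm2-7 signal, below the earlier limit of 90 for arguing against it, but 118 of them are ribosomal protein genes (0.27 alone), and the heat shock, glycolytic, galactose and mating pheromone genes lay at percentiles 65.2, 94.4, 95.2 and 97.7. Residual loading at sites used in wild type stays open: 12 of the 36 sites (33.3%) lay within 500 bp of a wild-type Mcm2-7 establishment site, but 3 of the 12 (YNR071C, FLO1 and YNR073C) are among the 5 above, and of the 31 others 9 lay there, against a mean of 3.03 and a maximum of 11 in 1000 random placements, 2 of which gave 9 or more. Among those 9, PES4 (1.66), ECM17-IML1 on chromosome 10 (1.23), XKS1-SKI6 on chromosome 7 (1.13), YHR218W on chromosome 8 (0.94) and YJL163C on chromosome 10 (0.64) also had strong ORC signal.

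The lower ORC signal in nocodazole-held orc6-td cells was uneven between sites. With the 350 Mcm2-7 sites ordered by ORC signal on the alpha-factor array, the median changes were -0.53 at the 117 weakest (-0.92 and -0.11 on the 2 pairs), -0.67 at the middle 116 (-0.88 and -0.47) and -0.02 at the 117 strongest (0.17 and -0.18). A single smaller factor for all sites would give the strongest sites the largest drop. The median ratio of orc6-td to wild-type signal was 0.31 at the weakest and 0.99 at the strongest sites, a difference of 0.69. It was taken over sites with a wild-type value over 0.5 (88 and 117), a cut that favours low ratios at the weakest. With each array's background subtracted the medians of all sites had ratios of 0.33 and 0.95. The ordering array correlated at 0.93 over probes with the orc6-td array of the first pair and shared its slide, which favours this pattern. On the second pair, of the other design, the background-subtracted ratios were 0.47 and 0.91, and only these argue against a single factor. A difference of the first array pair alone cannot be told apart from a change on both, since the change of -0.24 on the second pair, past the earlier limit of -0.2, lies within the spread between arrays of 0.39. The ordering came from an orc6-td array, other forms of unequal signal between arrays stay open, and so does the removal of Orc6 itself, which was not tested against them.

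A match to the ARS consensus sequence, the core of the ORC binding site in textbooks, was looked for in the 60-base probes of the second array design. Of the 742 probes within 500 bp of an ORC site centre 16 held it (2.16%), 4.31 times the 0.50% of probes elsewhere of the same A+T share, so base composition of the probes alone is argued against. For the 350 Mcm2-7 establishment sites the ratio was 2.41, with 15 of 1356 probes. Most ORC sites had no such probe, and the probes cover only part of each site.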
